A study of Drosophila melanogaster with 4 samples.

How the data were processed

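RNA polymerase II occupancy was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei from heads of adult Drosophila melanogaster of the wild-type laboratory strain Oregon-R, with an antibody from Abcam. The labels describe 4 samples, which are 2 ChIP libraries and 2 input libraries of unprecipitated chromatin, each input serving 1 ChIP library. Per the labels' protocols, heads were collected with sieves, the tissue was crosslinked with formaldehyde and the chromatin was sonicated.

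The authors deposited 3 region lists, 1 for each ChIP replicate and 1 for the replicate set. Each row of a list is called enriched or depleted, per the file headers and the type column, and carries 1 score per region. Coordinates are 1-based and refer to FlyBase release 5, per the file headers. Bowtie 0.12.7 is named in the submitters' processing notes. The region caller, its threshold, the handling of reads that map to several places and the way the replicates were combined are not given in the sources used here. The lists hold no read counts, so the depth of each library is unknown, and no interval that needs read counts is given. Because each list was made against input by the authors, no value of the input libraries themselves was used.

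The scale of the deposited score is not stated, so it was examined. Within each list the most common score was subtracted from every score. With base 2, the antilogarithm was a ratio of whole numbers (denominator up to 300, relative tolerance 1e-10) for 38.6% of the regions of replicate 1, 48.2% of replicate 2 and 22.9% of the replicate set. With base e the same test gave 0.194%, 0.129% and 0.235%, and with base 10 it gave 0.259%, 0.225% and 0.265%. The scores are therefore described as log2 values, with an offset that is not stated. They were used to describe, rank or filter regions within a list.

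Enriched regions of the 2 replicates were compared by overlap of at least 1 bp. Chance overlap was estimated from 1000 circular shifts of replicate 2 within each sequence, which keep the widths and the spacing of the regions, and p-values are one-sided. The smallest p these shifts can give is 0.001. Spearman correlation of scores was taken across overlapping pairs, with a 95% interval from 1000 bootstrap draws of 1 Mb windows. Regions are not independent replicates, so these values describe the libraries at hand. Binomial intervals of shares are exact (Clopper-Pearson, 95%) and cover the counting of regions only. Density was computed from region midpoints and from the sequence lengths in the file headers. Score percentiles of a chromosome were compared with those of the arms 2L, 2R, 3L and 3R by a two-sided test that permuted the labels of 100 kb windows 10000 times, whose smallest p is 0.0001. The 12 such tests were adjusted together by the Benjamini-Hochberg method. The change of the X difference between the 10th and 90th percentiles was tested in the same way in both replicates, after the median difference had been subtracted from X scores. Neighbouring windows are not fully independent. Shares of regions between chromosomes were compared with Fisher's exact test, two-sided. That test treats neighbouring regions as independent, so its p-values may be too small where regions cluster.

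The overlap test was tested on simulated data in which 6096 regions of replicate 1 were set against lists with a known percentage of positions in common. With 0% in common, 26.1% of regions overlapped against 26.2% in shifts. With 20%, 50% and 100% in common, the shares were 39.5%, 60.3% and 100%, each with permutation p = 0.004975, the smallest of that run. In the simulated lists regions had a single set width, and those not in common were placed at random, so clustering was not simulated. A score raised by 0.15 on X was found as a median difference of 0.16. There, scores had first been permuted over single regions, so likeness of neighbouring regions was not simulated either. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

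The overlap tests, the density of regions on each arm and the rule for naming regions were fixed before the data were examined. The tests of score percentiles, broad regions, regions without a partner and clustering, and the values along the arms, were chosen after that. The rule names the 10 highest-scoring and the 5 widest regions of the replicate set list that overlap a region of both replicates. Comparisons by gene had also been planned (promoter windows of 250 bp either side of a start, gene lists of head cell types and other tissues, RNA classes, and X or 4 against autosomes by gene). They needed an annotation of release 5. The gene table consulted is of Release 6 and coordinates were not carried between releases, so these comparisons were not run and no gene is named. The alternatives were the upper 50% and the upper 25% of each list by score, merging of regions within 500 bp, stricter overlap, leaving out each replicate and, added after seeing the data, the 6 arms 2L, 2R, 3L, 3R, X and 4 alone and a proximal stretch of 1, 3 or 4 Mb in place of 2 Mb.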

Results

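RNA polymerase II ChIP-seq of Oregon-R adult head nuclei was represented by 2 ChIP replicates, each compared by the authors with its own input, and by a list for the replicate set. Enriched regions numbered 6168 in replicate 1 and 6219 in replicate 2, a mean of 6193.5 ± 36.1 (SD, n = 2). Over all sequences they covered 22.5 Mb ± 0.20 (SD, n = 2). On the arms X, 2L, 2R, 3L, 3R and 4 alone, they covered 18.5% ± 0.165 of the length. These 6 arms held 98.8% of the regions of replicate 1 and 99.0% of those of replicate 2. The median width was 2571 bp in replicate 1 and 2521 bp in replicate 2, with an interquartile range of 2112 to 4103.5 bp and of 2137 to 4067 bp. The list for the replicate set held 6761 enriched regions over 26.5 Mb. The labels do not say whether the replicates came from separate fly collections, so p-values describe these libraries, and the spread between them is that of these samples only. Read depth is unknown, since the lists give no read counts.

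The first comparison asked whether both ChIP replicates marked the same places. RNA polymerase II regions lay at the same positions in the 2 replicates far more often than chance. In replicate 1, 5746 of 6168 regions (93.2%, 95% exact interval 92.5 to 93.8) overlapped a region of replicate 2. In replicate 2, 5824 of 6219 regions (93.6%, 93.0 to 94.2) overlapped one of replicate 1. The shared sequence came to 20.4 Mb, which is 83.1% of the sequence covered by either list. Circular shifts gave a mean overlap of 31.7% ± 0.756 (SD over shifts) of regions and 10.3% ± 0.366 of covered sequence. The highest share of regions in any shift was 41.9%. The permutation p by circular shifts was 0.001 for both measures, the smallest the shifts can give.

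The regions with the highest scores were found in both replicates, and regions without a partner were weaker and narrower. Each list was divided by score into 5 classes of nearly equal size. All 1234 regions in the highest class of replicate 1 and all 1244 in that of replicate 2 overlapped a region of the other replicate. In the lowest class the share was 75.5% in replicate 1 and 74.4% in replicate 2. The 422 regions of replicate 1 without a partner had a median score of 0.47 and a median width of 1660 bp, against 1.13 and 2692 bp for those with a partner. The 395 such regions of replicate 2 had a median score of 0.50 and a median width of 1626 bp, against 1.29 and 2661.5 bp. Across 6128 overlapping pairs the scores ranked alike, with Spearman's rho = 0.88 (95% bootstrap interval 0.87 to 0.89), and widths ranked less alike, with rho = 0.71 (0.69 to 0.73). Pairs of regions are not independent replicates. Of the 100 highest-scoring regions of replicate 1, 62 overlapped one of the 100 highest-scoring regions of replicate 2.

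**Figure D1:**
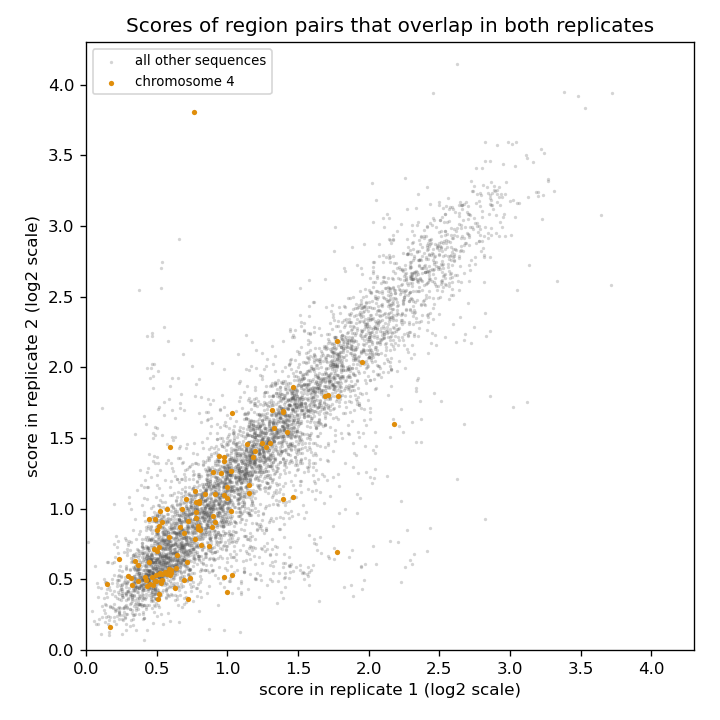
Score in replicate 1 (x axis) against score in replicate 2 (y axis), both on a log2 scale, for the 6128 pairs of enriched regions that overlap; each point is a pair, and pairs on chromosome 4 are orange. Scores rise together (rho = 0.88), and chromosome 4 pairs lie mostly at the low end.

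The list for the replicate set extended the replicate lists mostly at its weak end. Of its 6761 enriched regions, 5278 (78.1%, 95% exact interval 77.1 to 79.0) overlapped a region of both replicates, with a median score of 1.18. A further 363 overlapped replicate 1 alone and 344 replicate 2 alone, with median scores of 0.34 and 0.33. The remaining 776 (11.5%) overlapped neither and had a median score of 0.36 and a median width of 1276.5 bp. Of these, 409 were narrower than 1301 bp, the smallest width in either replicate list. At least 1 of the 776 scored high, the narrow region at 4 1324134 to 1325139, with a score of 3.29 and rank 11. Conversely, 99.5% of the regions of each replicate overlapped the set list.

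The 10 highest-scoring regions of the set list found in both replicates lay on 2L (4 regions), 2R (3), 3R (2) and 3L (1). Scores and positions are the authors' own. The highest was at 3R 17121187 to 17133238, with a score of 3.79, and ranked 1 in replicate 1 and 3 in replicate 2. A pair of regions on 2R, separated by 13.3 kb, ranked 2 and 4 in the set list. They spanned 8866874 to 8869581 (score 3.66, ranks 4 and 5 in the replicates) and 8882882 to 8886412 (score 3.54, ranks 5 and 4). The region at 3R 10956276 to 10958745 scored 3.61 and ranked 6 and 2. The regions at 3L 3068797 to 3073693 (score 3.36, ranks 11 and 13) and 2L 13546468 to 13551451 (score 3.35, ranks 14 and 12) also held nearly equal places in both replicates. The regions at 2L 15681954 to 15684387 (score 3.31) and 2L 2108663 to 2110966 (score 3.30) ranked 10 and 24, and 9 and 26. The remaining 2 of the 10 differed more. The region at 2R 14422262 to 14428764 (score 3.42) ranked 3 in replicate 1 and 109 in replicate 2. The region at 2L 10690523 to 10695150 (score 3.34) ranked 2 in replicate 1 and 494 in replicate 2. With 1 library on each side such a rank difference has no replicate check.

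Broad domains of enrichment held a sizeable part of the occupied sequence. Regions of 10 kb or more made up 3.73% of the regions and 15.1% of the covered sequence in replicate 1, and 3.31% and 13% in replicate 2. The widest region of the set list found in both replicates spanned 68.951 kb at 3R 5753443 to 5822393, with a score of 0.98. It was divided into 7 regions in replicate 1, 64816 bp in all, and into 4 in replicate 2, 64204 bp in all. The next widest spanned 45.904 kb at 2L 9255487 to 9301390 (score 1.43), 44.928 kb at 3R 5242555 to 5287482 (1.45), 43.516 kb at 2L 13017745 to 13061260 (1.37) and 40.526 kb at X 2535107 to 2575632 (1.196). None of the 5 widest was among the 10 highest-scoring. Across all regions, wider ones tended to score higher, with Spearman's rho of 0.56 in replicate 1 and 0.57 in replicate 2.

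The density of regions was compared between chromosomes and along each arm. Chromosome 4, the small and largely heterochromatic autosome, was the most densely occupied of the 6 arms. It held 84.3 ± 2.09 regions per Mb (SD, n = 2), and 38.4% ± 0.795 of its length was covered. The other autosomal arms ranged from 46.5 ± 0.922 regions per Mb on 2L to 57.1 ± 0.167 on 2R, with 47.4 ± 0.461 on 3L and 51.4 ± 0.177 on 3R. Their covered share was between 16.6% ± 0.123 on 2L and 20.7% ± 0.248 on 2R. Relative to these arms pooled, chromosome 4 had 1.65 times the regions per Mb in replicate 1 and 1.69 times in replicate 2, and 2.14 and 2.10 times the covered share. These differences exceeded the spread between replicates and were not tested. The order turned round among high-scoring regions. In the upper 50% of each list by score, chromosome 4 held 0.664 times the autosomal density, and in the upper 25% it held 0.291 times.

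Regions on chromosome 4 were weaker and more often broad. Their median score was 0.65 in replicate 1 and 0.73 in replicate 2, against 1.07 and 1.21 on 2L, 2R, 3L and 3R. The difference of -0.41 in replicate 1 and -0.47 in replicate 2 had adjusted p = 0.0032 and 0.0026 by permutation of 14 windows on chromosome 4 among all windows. Regions of 10 kb or more made up 10 of 112 regions on chromosome 4 in replicate 1 (8.93%, against 3.55% on the other autosomes) and 10 of 116 in replicate 2 (8.62% against 3.21%). Fisher's exact test gave adjusted p = 0.0152 in both replicates, over 4 such tests. It takes regions as independent, so these values may be too small.

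The X chromosome, which is single in males and paired in females, carried regions at a density close to the autosomes. Its 50.8 ± 0.410 regions per Mb (SD, n = 2) lay within the range of the autosomal arms, as did its covered share of 18.9% ± 0.351. The ratio to the pooled arms was 1.01 in each replicate, and it was 0.994 after regions within 500 bp were merged. For the covered share the ratio was 1.05 in replicate 1 and 1.03 in replicate 2. In the set list the ratios were 1.04 for regions per Mb and 1.11 for the covered share, neither tested. The median score on X was 1.13 in replicate 1 and 1.32 in replicate 2, above the autosomal medians by 0.07 (adjusted p = 0.0667) and 0.11 (adjusted p = 0.0057) by permutation of windows. The set list, in contrast, had nearly equal medians, 0.938 on X and 0.937 on the autosomal arms. The 10th percentile was higher on X by 0.09 in replicate 1 and 0.16 in replicate 2 (permutation of windows, adjusted p = 0.0003 in both). The 90th percentile differed by -0.04 and -0.02, with adjusted permutation p = 0.6789 and 0.8627. The difference at the 10th percentile exceeded that at the 90th by 0.13 in replicate 1 and 0.17 in replicate 2 (permutation of windows after removing the median difference, adjusted p = 0.0149 and 0.0086, over 2 tests). Regions of 10 kb or more made up 4.24% and 3.40% of X regions, and the difference from the autosomes did not pass the test (adjusted p = 0.341 and 0.712, Fisher's exact test).

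**Figure D2:**
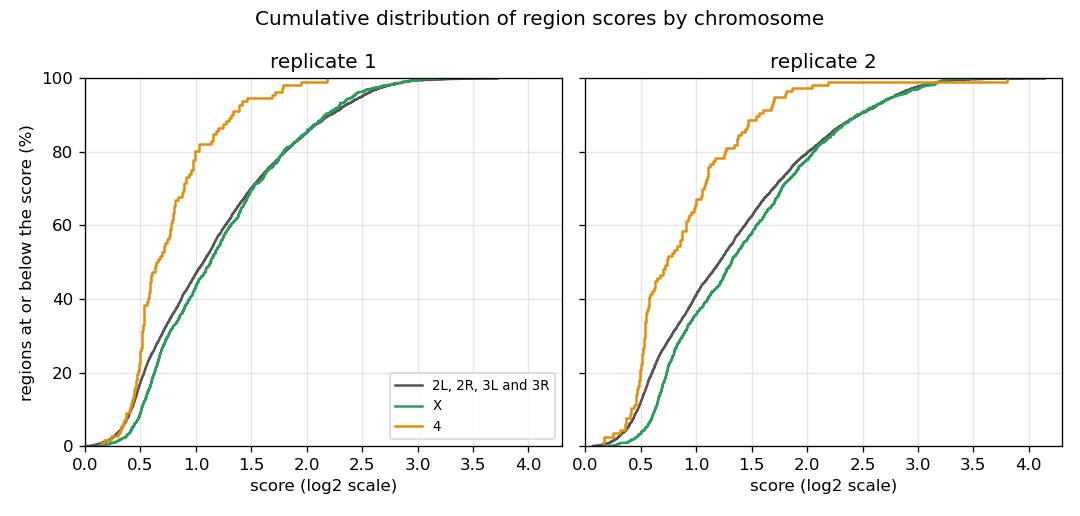
Percentage of enriched regions (y axis) at or below each score on a log2 scale (x axis) in replicate 1 (left) and replicate 2 (right), for the pooled arms 2L, 2R, 3L and 3R, for X and for chromosome 4. The chromosome 4 curve rises earliest (medians 0.65 and 0.73), and the X curve lies to the right of the autosomal one at low and middle scores (medians 1.13 and 1.32, against 1.07 and 1.21; the median difference in replicate 1 did not pass the test).

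Pooled heterochromatic sequence outside the arms carried few regions. The 6 scaffolds assigned to heterochromatin of X, Y, 2L, 2R, 3L and 3R, 9.28 Mb in all, held 46 regions in replicate 1 and 42 in replicate 2. Their density was 4.74 ± 0.305 regions per Mb (SD, n = 2), and 1.58% ± 0.0793 of their length was covered, against 50.4 ± 0.322 and 18.1% ± 0.113 on the autosomal arms. Their median scores were 0.98 and 1.25, against 1.07 and 1.21 on the autosomal arms. The X scaffold, of 0.204 Mb, stood above the other scaffolds, with 5 and 3 regions, a density of 19.6 ± 6.93 per Mb (SD, n = 2) and 10.9% ± 0.821 of its length covered. The Y scaffold held 1 region in replicate 1, with a score of 0.64, and 0 in replicate 2. Unplaced sequence (U) held 26 and 20 regions, and the additional unplaced sequence (Uextra) held 0 in every list. Reads from repeated sequence can be lost or shared between copies in mapping, and how they were handled is not given in the sources used here.

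Along the arms, enriched regions were clustered and thinned out towards the centromeric end of most assembled arms. The variance of counts per 100 kb window was 2.19 times the mean in replicate 1 and 2.22 times in replicate 2, against 1.05 and 1.04 for random placement (one-sided permutation p = 0.001 in both, the smallest that 1000 random placements can give). Windows without a region numbered 80 and 76 of 1202, where random placement left a mean of 8.28 and 7.67 empty. Random placement takes no account of where genes lie or of reads lost in repeated sequence. The test therefore shows only that regions were not spread at random, and no cause was tested. Over 118 full bins of 1 Mb the 2 replicates ranked the bins alike, with Spearman's rho = 0.96 across bins. The bins and stretches named here were chosen after their values were seen. The densest bin outside chromosome 4 was 20 to 21 Mb on 3R, with 76 and 83 regions, followed by 5 to 6 Mb on 2R, with 76 and 82. The sparsest was 23 to 24 Mb on 3L, with 12 and 9.

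The 2 Mb at the centromeric end of each assembled arm were compared with the rest of that arm. The heterochromatic scaffolds are separate sequences and no part of these stretches, so the stretches need not adjoin the centromere. Density there was 16.3 ± 1.77 regions per Mb (SD, n = 2) on 3L against 50.1 ± 0.659 on the rest of that arm. It was 28.8 ± 3.89 against 53.0 ± 0.831 on X, 30.8 ± 0.354 against 59.9 ± 0.222 on 2R, and 31.8 ± 1.06 against 47.9 ± 0.909 on 2L. On 3R the direction depended on the length taken. The first 2 Mb of the assembled arm held 58.0 ± 2.12 against 50.9 ± 0.0273 on the rest, a mean ratio of 1.14. The 2 to 3 Mb bin held 27 and 24 regions, however, and with 3 Mb the ratio was 0.909. The 3 longest stretches without a region in either replicate measured 460.943 kb at 3L 24068558 to 24529500, 391.052 kb at 3R 2486367 to 2877418 and 370.553 kb at 3L 23336769 to 23707321. A stretch of 342.381 kb at X 21502255 to 21844635, one of 324.347 kb at 3R 12482399 to 12806745 and one of 281.949 kb at X 7219407 to 7501355 followed. In all, 129 stretches of at least 100 kb without a region made up 16.3% of the 6 arms.

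**Figure D3:**
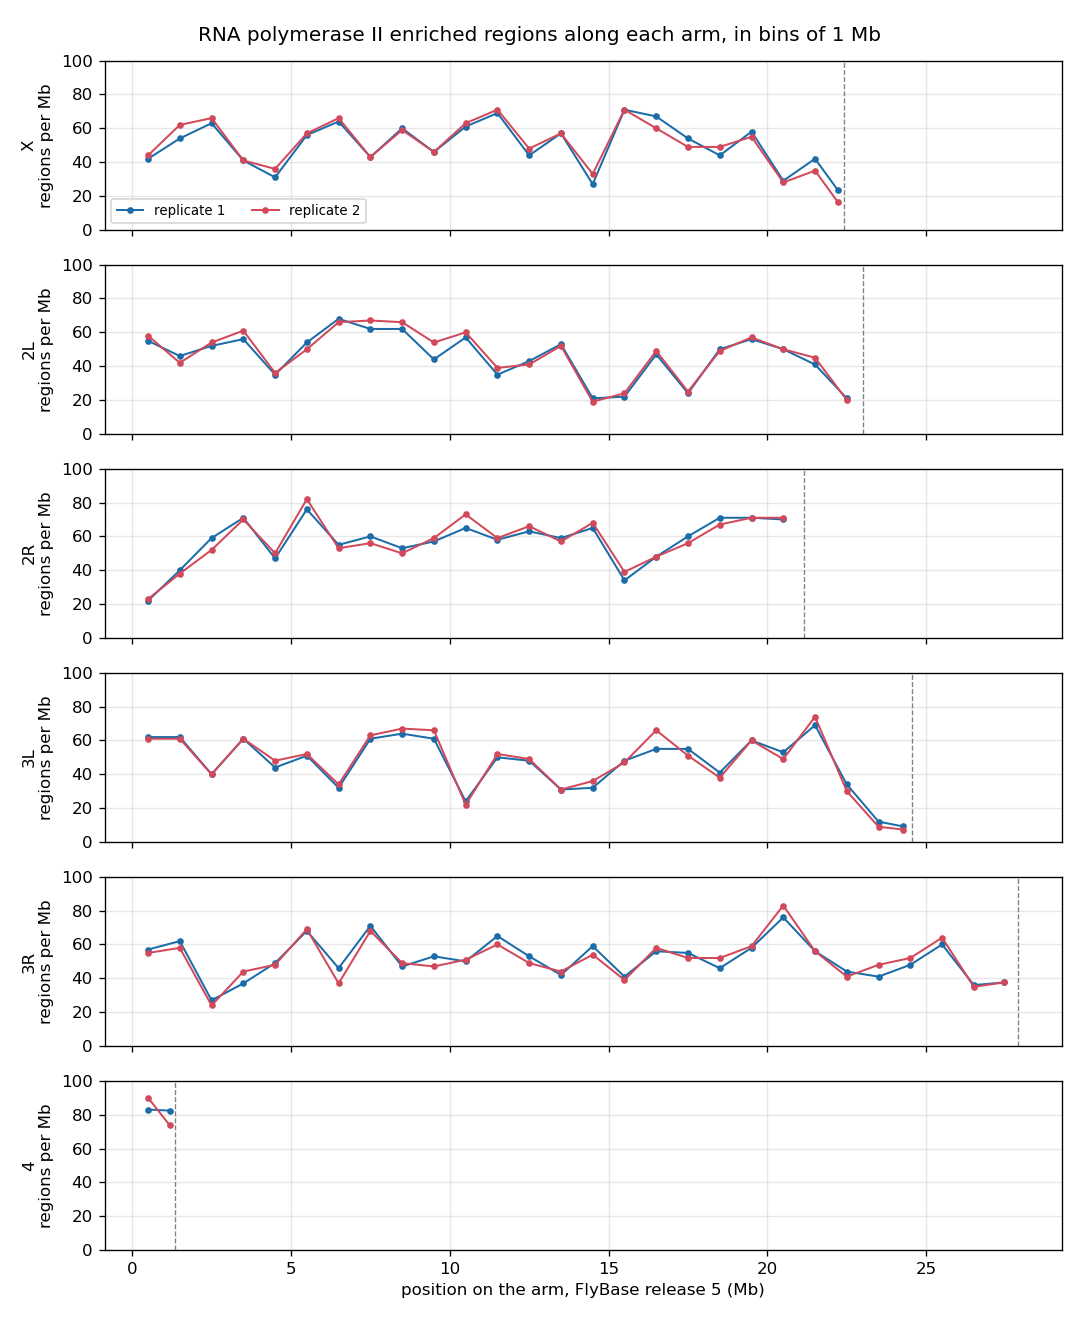
Enriched regions per Mb (y axis) in bins of 1 Mb along each arm (x axis, position in Mb on FlyBase release 5) for replicate 1 and replicate 2; dashed lines mark the end of the assembled arm, and last bins that hold under 0.3 Mb are left out. Both replicates follow similar profiles (rho = 0.96 across bins), and the first bin of chromosome 4 is the highest (83 and 90 regions). Density is lower in the 2 Mb at the centromeric end of the assembled arms X, 2L, 2R and 3L (right end of X, 2L and 3L, left end of 2R). On 3R it is low at 2 to 3 Mb.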

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

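All tests in this part, and the regions named, were chosen after the result was seen. The list for the replicate set holds 41 regions called depleted rather than enriched, which enter none of the comparisons above. Replicate 1 holds 3 such regions and replicate 2 holds 0. The 41 lay on 3L (13), 2R (11), 3R (9), 2L (6) and 4 (2), and were 1494 to 1848 bp wide. Their scores ran from -0.23 to -0.0015, with a median of -0.03, whereas 96.0% of the enriched regions of that list had a score above the size of the lowest of them. The lowest was at 2R 3978417 to 3980090, where replicate 1 had an enriched region with a score of 0.06 and replicate 2 had none. At 3L 15296507 to 15298290, 1 of the 5 places called enriched in both replicates, the set list gave -0.18. The enriched regions there had scores of 0.16 in replicate 1 and 0.11 in replicate 2. In the set list every enriched region scored above 0 (lowest 0.0034), so the sign there goes with the call. The lowest enriched scores were also above 0 in replicate 1 (0.013) and replicate 2 (0.064). The score offset is not stated, so the sizes of scores in different lists cannot be set against each other.

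Of the 41 depleted regions, 32 (78.0%, 95% exact interval 62.4 to 89.4) overlapped an enriched region of at least 1 replicate, against a mean of 11.7 and at most 20 in 1000 circular shifts (p = 0.001, the smallest the shifts can give, one-sided). The overlap was with replicate 1 for 19 regions and with replicate 2 for 18, and with both for 5. The count of 32 lay above the highest shifted count of 20, so depleted and enriched calls shared positions more often than shifted ones. It cannot tell whether these sites are truly depleted of RNA polymerase II in these nuclei. The lists come from the same libraries, and the shifts place regions anywhere on a sequence. Calls of either sign may therefore coincide more often than in shifts. Only 5 of the 41 were called enriched in both replicates, which does not settle the question either. Of the 3 depleted regions of replicate 1, 2 overlapped an enriched region of replicate 2 and 2 overlapped a depleted region of the set list. A candidate explanation is that the depleted regions of the set list are the low end of one set of calls, with the sign set by a score close to 0. The 41 enriched regions of the set list with the lowest scores overlapped a region of at least 1 replicate in 31 cases (Fisher's exact test, p = 1) and of both in 8, and had a median width of 1725 bp against 1739 bp. A test on 41 against 41 regions of one list cannot show that the 2 sets are alike, so this explanation stays a candidate. For the 9 depleted regions without an enriched partner, true depletion stays open too, because the lists give no replicate scores there.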

How the results depend on the processing

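The restriction to the 6 arms and the lengths of the proximal stretch were chosen after seeing the data, the other alternatives before. The overlap between replicates stayed above chance under these 6 alternatives (permutation p = 0.001 by circular shifts in each). It was 92.6% of regions when 50% of the shorter region had to be shared, 85.4% when 50% of each region had to be, 92.7% and 88.5% in the upper 50% and upper 25% by score, 94.0% after merging and 93.5% on the 6 arms alone. The mean number of regions fell by construction to 3097 and 1548.5 in the upper 50% and upper 25%, was 5606 after merging, and was 6168 to 6219 with either replicate left out. The density of chromosome 4 relative to the other autosomes (1.67) was 1.53 after merging within 500 bp and turned below 1 in the upper 50% (0.664) and upper 25% (0.291), where a score limit removed more of the lower-scoring regions of chromosome 4. The same ratio for X (1.01) was 1.10 in the upper 50%, 1.07 in the upper 25% and 0.994 after merging, on the other side of 1; the cause was not tested. With 1 replicate left out, the ratio was 1.65 or 1.69 for chromosome 4 and 1.006 or 1.009 for X, which are the values of the single replicates and no test of stability. The ratio of proximal to remaining density on 3R (1.14 with 2 Mb) was 1.09 with 1 Mb and fell below 1 with 3 Mb (0.909) and 4 Mb (0.869), whereas on 2L, 2R, 3L and X it stayed below 1 with each length, between 0.153 and 0.886. Rank correlation of scores rose to 0.95 over pairs that shared 50% of each region and was 0.71 for widths, and the share of set regions found in both replicates was 71.5% under that stricter overlap; the cause was not tested. No paired analysis was possible because the lists give 1 score per region after comparison with input, with no separate ChIP and input values. The alternatives for comparisons by gene (promoter windows of 500 and 100 bp, the upper 50% by score, each replicate alone, the set list, gene bodies, genes with isolated starts) were not run, since they needed an annotation of release 5. Depth is unknown, so how many weak regions it hides could not be estimated.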

Other observations

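The tests in this part, and the regions named, were chosen after the data were seen, except the merging of regions on chromosome 4. A few strong regions differed in rank between the replicates. Of the 100 highest-scoring regions of replicate 1, 6 ranked beyond 500 in replicate 2, and of the 100 highest of replicate 2, 5 ranked beyond 500 in replicate 1. The region at X 9943297 to 9950909 ranked 31 in replicate 1 (score 3.02) and its counterpart ranked 1830 in replicate 2 (1.72). In unplaced sequence U, the region at 8055151 to 8057485 ranked 22 in replicate 1 (3.12) and 1736 in replicate 2 (1.75). The right end of chromosome 4 differed most. Replicate 2 had a region at 1335289 to 1337268, 14.589 kb from the end of the assembly, with a score of 3.81 and rank 6, the highest score on this chromosome in that list. In replicate 1 the region overlapping its edge, at 1333711 to 1335477, scored 0.76 and ranked 4074. In the set list the same stretch scored 0.83, while a separate region at 1324134 to 1325139 scored 3.29 and ranked 11, where neither replicate list had a region. That region was narrower than 1301 bp, the smallest width in either replicate list, so its absence there cannot be read as disagreement. With 1 library on each side the rank differences between replicates could not be tested.

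Regions without a partner in the other replicate were more frequent on X than on 2L, 2R, 3L and 3R in replicate 1, with 105 of 1133 (9.27%) against 294 of 4851 (6.06%) and adjusted p = 0.000799 by Fisher's exact test. In replicate 2 the shares were 86 of 1146 (7.50%) and 292 of 4895 (5.97%), with adjusted p = 0.115 by the same exact test, over 4 tests that included chromosome 4.

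The median score on X was above the autosomal one by 0.11 in replicate 2 (adjusted permutation p = 0.0057) and by 0.07 in replicate 1, where it did not pass the test (adjusted permutation p = 0.0667), and the medians were nearly equal in the set list (0.938 and 0.937). Scores on X higher by the same amount throughout the list are argued against, since the difference at the 10th percentile exceeded that at the 90th by 0.127 in replicate 1 and 0.171 in replicate 2 (adjusted permutation p = 0.0149 and 0.0086). A higher score needed for a call on X remains open, since the 10th percentile on X was higher by 0.091 in replicate 1 and 0.16 in replicate 2 (adjusted p = 0.0003 in both, permutation of 100 kb windows). In the set list the 10th percentile was higher on X by 0.075 and the 90th differed by -0.074, neither tested. There, 0 regions on X were called depleted, beside 1278 enriched, against 39 beside 5311 on the autosomal arms (Fisher's exact test, p = 0.000347). That p may be too small, since the test takes neighbouring regions as independent. As a hypothesis, fewer X reads may raise the ratio a region needs to be called, if the population held males. This was not tested, because the labels do not give the sexes and the lists give no reads per arm.

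Chromosome 4 held more regions per Mb with lower scores than the other autosomes. Splitting of its regions at gaps of up to 500 bp is argued against as the whole cause of the density. The density ratio was 1.67 as deposited and 1.53 after merging regions within 500 bp, so such splitting may account for a part. Wider gaps were not tried. A different mix of region widths is argued against as the whole cause. Against autosomal regions drawn with the same width deciles, the median score on chromosome 4 differed by -0.34 in replicate 1 and -0.31 in replicate 2. Without matching the differences were -0.41 and -0.47, so widths may account for a part. The matched differences exceeded 2 permutation SDs (0.122 and 0.138) in each replicate. These SDs belong to the unmatched difference, and no permutation was run on the matched one. A lower score needed for a call on 4 is argued against as the whole cause too, since the 10th percentile differed by -0.01 and -0.050 while the 90th percentile differed by -0.89 and -0.91 (adjusted permutation p = 0.0003 in both). Loss or sharing of reads in repeated sequence was not tested and remains open, and no biological explanation was tested.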
